A study of Mus musculus with 8 samples.

How the data were processed

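Hippocampal RNA from 8 female mice was measured on 1-colour Agilent expression microarrays, with 1 array per mouse. Per the labels, all 8 were nontransgenic littermates from a transgenic line. Of these, 4 were untreated (Control) and 4 received hydroxyurea in the drinking water at 45 mg/kg/day for 10 weeks (Hydroxyurea). Per the labels' protocols, 200 ng of RNA per sample was labelled with Cy3. The arrays lay on 1 slide that was scanned once. The Control arrays took row 1 and the Hydroxyurea arrays row 2, so slide row and group cannot be told apart. The labels state that cages were shared, but not which mice shared one.

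Per the file headers, the scans were read with Feature Extraction 12.0.3.1, which gave each spot a processed signal intensity, background-subtracted within the array and not normalized between arrays. The same deposited files hold the median signal intensity of each spot and of its local background, and flags for outlier spots and for spots well above background. The value table that the authors deposited holds a z score of the log signal over the 62976 features of an array. A recomputed z score differed from it by at most 0.005. Its columns have medians from -0.21 to -0.17, and its scale is a z score rather than log2, so it was used for counts of genes and lists and not for fold changes. The build in the headers, mm9 (NCBI37), is not that of the gene table used for names, GRCm38.p6, and no coordinates are given.

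Of 55681 non-control probes, 28331 carried a RefSeq accession of 1 gene in that table, and these named 21368 genes. The other 27350 probes entered only the fit of every probe. Log2 of the processed signal minus the 75th percentile of that array was the main value. Spots of a probe were averaged, leaving out those marked as outliers. For 5754 genes with over 1 probe, the probe with the highest mean over all arrays stood for the gene. A gene was tested if its probe was well above background on at least 4 of 8 arrays and had a value on at least 6, which left 16618 genes. Signal over background sets the precision here: the percentage of probes well above background was 62.1 to 76.7 on the Control arrays and 59.6 to 69.0 on the Hydroxyurea arrays, and 4 arrays per group limit it further. No spot was saturated.

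Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Mice of 24 and of 19 weeks within the Hydroxyurea group were compared in a fit with 3 group means over all 8 arrays. Intervals are 95% intervals of the fit of Hydroxyurea against Control. A fixed set of 49 gene lists, covering pathways, cell types, hippocampal and neighbouring regions, blood and leukocytes, was tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. A list needed at least 5 genes tested. Each mouse also received a score for each list, the mean over members of the log2 value minus that gene's mean over the 8 arrays. The 19 scores of cell types, regions, blood and leukocytes were compared by an exact two-sided permutation test over 70 assignments, which cannot give a p below 0.0286. Where all arrays of 1 group lay below the background limit, a fold is given as a lower bound, from the bright group's mean and, on each dim array, the higher of the probe's signal and the lowest signal well above background.

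The named genes follow a rule set before the data were examined, as were the lists, tests and most alternatives. It takes 12 genes per direction for treatment and 5 per direction for age, filled by the smallest unadjusted p where too few passed, without clone or locus names, then up to 4 members of each list by smallest p, and a fixed set that includes Rrm1, Rrm2, Rrm2b, Bdnf, Arc, Ttr and Dcx. The text gives part of those list members, and some items are not reported here.

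The fit was tested on simulated data with 200 genes of 16585 changed in the treatment comparison. It called 50.7% of those changed 1.5-fold, 76.1% of those changed 2-fold and 87.9% of those changed 3-fold, and 6 unchanged genes. In the age comparison it called 20.9%, 52.2% and 77.3%, and 6 unchanged genes. With a list shifted 1.2-fold and independent errors, camera found the shift of the immediate early and glycolysis lists and not of the choroid plexus list. In the run with the glycolysis list shifted, 1 other list passed as well.

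The alternatives were quantile, median and z scaling, normexp background correction, the value table, other filters and probe rules, age as a covariate, 19-week mice only, the replicate number as a block, other variance models and thresholds, and leaving out each array. Normexp with an offset of 50 had been planned on the mean spot signal, which was not used here, and was run on the median signal instead. That choice, the fits with list scores as covariates and the fit without 2 doubted arrays were added after seeing the data, and the bound for the dentate gyrus covariate was written before its result was seen. Figures were drawn with matplotlib 3.10.9.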

Results

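Hydroxyurea inhibits ribonucleotide reductase, the enzyme that makes deoxynucleotides for DNA synthesis. The series sets hippocampal RNA of treated mice against that of untreated mice, and its title concerns protection of hippocampal neurons and memory. Each group held 4 mice. The Control mice were 19 weeks old, Hydroxyurea 1 and 2 were 24 weeks old, and Hydroxyurea 3 and 4 were 19 weeks old. The 75th percentile of the signal was 1677 to 2417 on the Control arrays. It was 1052 on Hydroxyurea 2 and 1680 to 2162 on the other Hydroxyurea arrays. Replicate spots varied by a median of 12.1% on Control 1 and by 3.15% to 3.45% on the other Control arrays. Arrays correlated with each other at 0.981 to 0.997 across genes, which are not independent replicates.

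No gene passed the threshold between treated and untreated hippocampus. Among genes with higher values after treatment, Ltf, the lactoferrin of neutrophil granules, had a log2 fold change of 0.69 ± 0.12 (SE, n = 4 per group; limma adjusted p = 0.452). Tmsb10, an actin-binding thymosin, had 0.44 ± 0.09. Among genes with lower values, Igf1r, the receptor of insulin-like growth factor 1, had -0.32 ± 0.06, and Net1, a guanine nucleotide exchange factor, had -0.46 ± 0.08. Cbfb, a subunit of core-binding transcription factors, had -0.27 ± 0.05. The 4 treated values of each of these genes lay outside the range of the 4 Control values. Ltf was dim, with a mean scaled log2 signal of -5.03 in Control and -4.35 in Hydroxyurea mice. Its probe was well above background on 4 arrays of each group. The lowest log2 signal well above background, before scaling, was 4.32 to 5.05 on Control arrays and 4.90 to 5.68 on Hydroxyurea arrays. Whether this difference in background raised the Ltf value was not tested.

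The other higher values were those of Lalba (0.48 ± 0.09), Krt1 (0.47 ± 0.10), Pcp2 (0.56 ± 0.11), Astn2 (0.52 ± 0.11), Camp (0.36 ± 0.08), Pdcd1 (0.45 ± 0.10), Lhb (0.58 ± 0.12), Rsph6a (0.56 ± 0.12), Mamstr (0.31 ± 0.07) and Olfr700 (0.57 ± 0.12). The other lower values were those of Pot1b (-0.45 ± 0.06), Cenpu (-0.46 ± 0.07), Slc15a2 (-0.45 ± 0.08), Agmat (-0.37 ± 0.07), Dusp12 (-0.29 ± 0.05), Grasp (-0.32 ± 0.06) and Sbk3 (-0.42 ± 0.08). A second probe of Cenpu had the opposite sign, and Pot1b had a value of 0.0026 with normexp background correction. Rsph6a was well above background on 3 Control and 2 Hydroxyurea arrays, and Pot1b on 4 and 2. Erg was well above background on 4 Control arrays and on 0 Hydroxyurea arrays and was at least 1.08-fold lower. Inhbc had the same pattern of detection, and no fold is given for it. The adjusted p of every gene in this paragraph was 0.452 in the limma fit.

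Of 16618 genes tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 586 higher and 1056 lower, against 830.9 in all by chance, and 64.3% of them were lower. That percentage was 90.8 when each array was centred on its median and 56.4 with normexp. With no filter on dim probes the majority turned, with 1508 genes higher and 975 lower. The total was 2522 without Control 1 and 3249 with array weights, and 1103 with 19-week mice only and 1110 without Control 4. The 2 groups did not overlap for 7.49% of genes, where chance gives 2.86% on average. That share was not computed for other splits of the mice, and slide row and group cannot be told apart. The unadjusted total was reached by 4 of 35 splits of the mice into 4 and 4, the real one included. The 95% interval excluded a 1.5-fold change for 77.7% of genes.

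**Figure D1:**
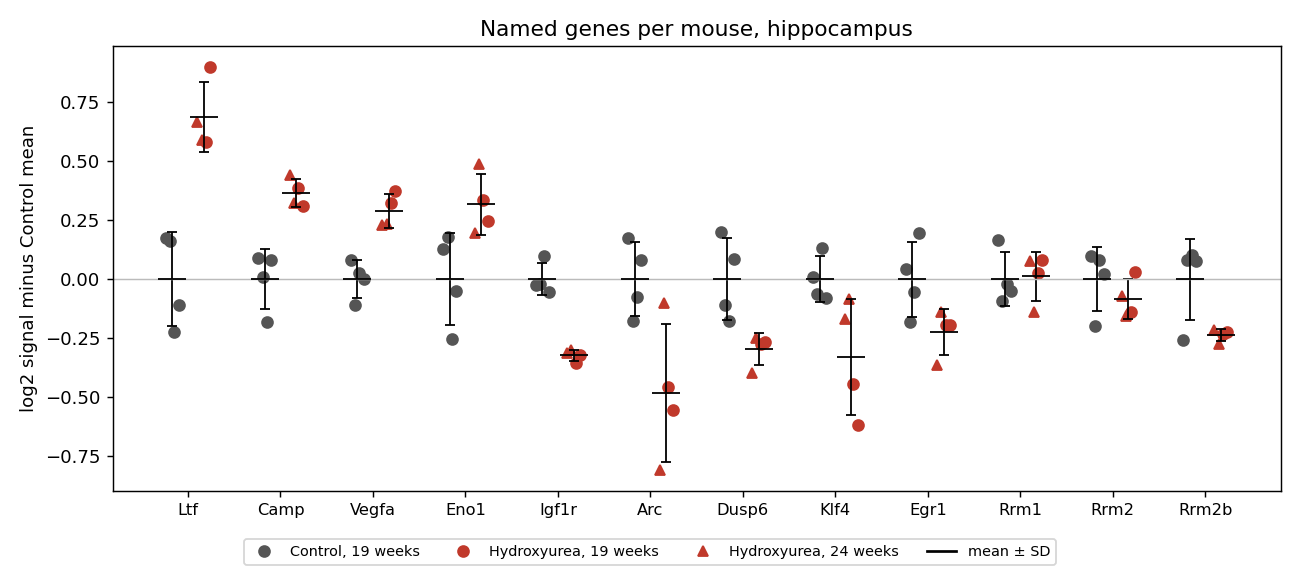
Log2 signal of 12 named genes in each mouse, minus the Control mean of that gene. Grey points are Control and red points Hydroxyurea mice, triangles mark the 24-week mice, and bars give mean ± SD over 4 mice. Igf1r had a log2 fold change of -0.32 and Rrm1 of 0.01.

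The target of the drug was examined first through the subunits of ribonucleotide reductase. Rrm1, the large subunit, had a log2 fold change of 0.01 ± 0.08 (SE, n = 4 per group), with a 95% interval from -0.18 to 0.20. It was -0.07 with median centring. Rrm2, the small subunit of dividing cells, had -0.08 ± 0.08, with an interval from -0.28 to 0.11. Rrm2b, the small subunit induced by p53, had -0.24 ± 0.09, with an interval from -0.44 to -0.03, and its value in Control 1 (-1.49) stood apart from the other Control mice (-1.15 to -1.13). Exact permutation p-values were 0.886, 0.343 and 0.114, and 0.886, 0.514 and 0.343 after adjustment over these 3 genes. The lowest possible p of 0.0286, adjusted over 3 genes, does not let a single gene pass, so the adjusted values say little. Genes of dNTP supply had 8 members higher and 10 lower of 18 (camera adjusted p = 0.779).

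Choroid plexus genes had higher values in the treated group for 18 of 18 members, with a median log2 fold change of 1.28. Ttr, the transthyretin that this epithelium secretes, had 1.30 ± 1.03 (SE, n = 4 per group) from a log2 signal of 4.83 ± 1.69 in Control and 6.13 ± 1.66 in Hydroxyurea mice (SD), Otx2 had 1.37 ± 0.70 with Hydroxyurea 4 apart from its group, Prlr 1.30 ± 0.73 and Slco1a5 1.98 ± 0.99. The list passed camera (adjusted p = 0.00021) and was lost with an estimated correlation (adjusted p = 0.826). The score per mouse was -2.02, -0.97, 0.84 and -0.34 in Control 1 to 4. It was -1.08, 0.80, 0.09 and 2.69 in Hydroxyurea 1 to 4, so the groups overlapped. The SD of the score was 1.19 in Control and 1.58 in Hydroxyurea mice, against a difference of 1.25 between the groups. The exact permutation p of the score was 0.286. Its adjusted p was 0.875, but that adjustment does not let a single score pass. The score difference of 1.25 was 0.56 without Hydroxyurea 4 and 0.78 without Control 1. Ependymal genes, which mark the ventricle lining, had 14 of 15 members higher (camera adjusted p = 0.0579), with scores of -1.37, -0.16, 0.50 and -0.05 in Control 1 to 4 and 0.48, -0.30, -0.38 and 1.27 in Hydroxyurea 1 to 4. Their score difference of 0.54 was 0.17 without Control 1 (camera adjusted p = 0.480) and 0.21 without Hydroxyurea 4 (0.439). Without the noisy array Control 1 and the dim array Hydroxyurea 2, a fit chosen after seeing the data, the adjusted p of the choroid plexus list was 0.102.

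Peripheral leukocyte genes had higher values in 12 of 15 members, with a median log2 fold change of 0.28. Camp, a neutrophil granule peptide, had 0.36 ± 0.08 (SE, n = 4 per group), and its limma p was 0.021 adjusted over the list alone and 0.452 over all genes. Ccr7, a homing receptor of lymphocytes that was well above background on 2 arrays of each group, had 0.55 ± 0.19, Cd3e of the T cell receptor complex 0.31 ± 0.11 and S100a9 of neutrophils 0.66 ± 0.29. The list passed camera (adjusted p = 0.0022), and was lost over all mice with an estimated correlation (adjusted p = 0.826) and with fry (adjusted p = 0.465). At the preset correlation it was lost in 19-week mice (adjusted p = 0.0744) and with age as a covariate (0.111), which give the same fold changes. The deposited value table (0.0911) and the fit without Control 1 and Hydroxyurea 2 together (0.0792) lost it as well. The score per mouse did not separate the groups (exact permutation p = 0.143).

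Presynaptic vesicle genes had higher values in 18 of 20 members, with a median log2 fold change of 0.10. Syp had 0.22 ± 0.10 (SE, n = 4 per group) and Stx1a 0.22 ± 0.10, which encode a protein of the vesicle membrane and one of vesicle fusion. Glycolytic genes had higher values in 19 of 23 members, with a median of 0.12. The enolase gene Eno1 had 0.32 ± 0.11, Pgk1 0.13 ± 0.06, the pyruvate kinase gene Pkm 0.17 ± 0.08 and Pdk1 0.13 ± 0.05. Both lists passed camera (adjusted p = 0.0123 and 0.0128) and were lost with an estimated correlation (adjusted p = 0.826 for each). Cytosolic ribosomal protein genes, listed as an indirect check of RNA quality and depth, had higher values in 19 of 25 members (camera adjusted p = 0.163). RNA quality itself was not measured here. The dim array Hydroxyurea 2 had the highest score for them (0.15), as for presynaptic (0.15) and glycolytic genes (0.12). The presynaptic and glycolytic lists each passed in 11 of 22 other settings. Both were lost with quantile scaling (adjusted p = 0.0511 and 0.0922), without Control 4 (0.0539 and 0.112) and without Hydroxyurea 2 (0.112 for each). They were also lost in 19-week mice only (0.242 and 0.121) and with age as a covariate (0.275 and 0.133), which give the same fold changes.

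Immediate early genes, which neurons transcribe within minutes of activity, had lower values in 17 of 22 members, with a median log2 fold change of -0.22. Arc, which acts at active synapses, had -0.48 ± 0.15 (SE, n = 4 per group), Dusp6 had -0.30 ± 0.09, Klf4 -0.33 ± 0.12, Egr1 -0.22 ± 0.09 and Fos -0.30 ± 0.20. The score of this list was 0.02 to 0.13 in Control and -0.19, 0.12, -0.09 and -0.17 in Hydroxyurea 1 to 4 (exact permutation p = 0.114). The list passed camera (adjusted p = 0.0128) and was lost with an estimated correlation (adjusted p = 0.826). It was also lost without Control 1 (0.156), Hydroxyurea 1 (0.117) or Hydroxyurea 4 (0.0927), and with the dentate gyrus score as a covariate (0.120). Dentate gyrus genes had 13 of 17 members lower (camera adjusted p = 0.104), with Trpc6 at -0.39 ± 0.14, and passed in 7 of 22 other settings, 19-week mice only among them (adjusted p = 0.0105). For dentate gyrus genes the adjusted p was 0.890 with an estimated correlation and 0.424 without Control 4, where the score difference was -0.05 in place of -0.14. Glucocorticoid-induced genes had 18 of 20 lower (camera adjusted p = 0.0629), with Errfi1 at -0.33 ± 0.09 and Sgk1 at -0.47 ± 0.29. The glucocorticoid score was 0.55 in Control 3 and -0.16 to 0.08 in the other Control mice, and without Control 3 the camera adjusted p was 0.633 and the score difference -0.04 in place of -0.19.

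**Figure D2:**
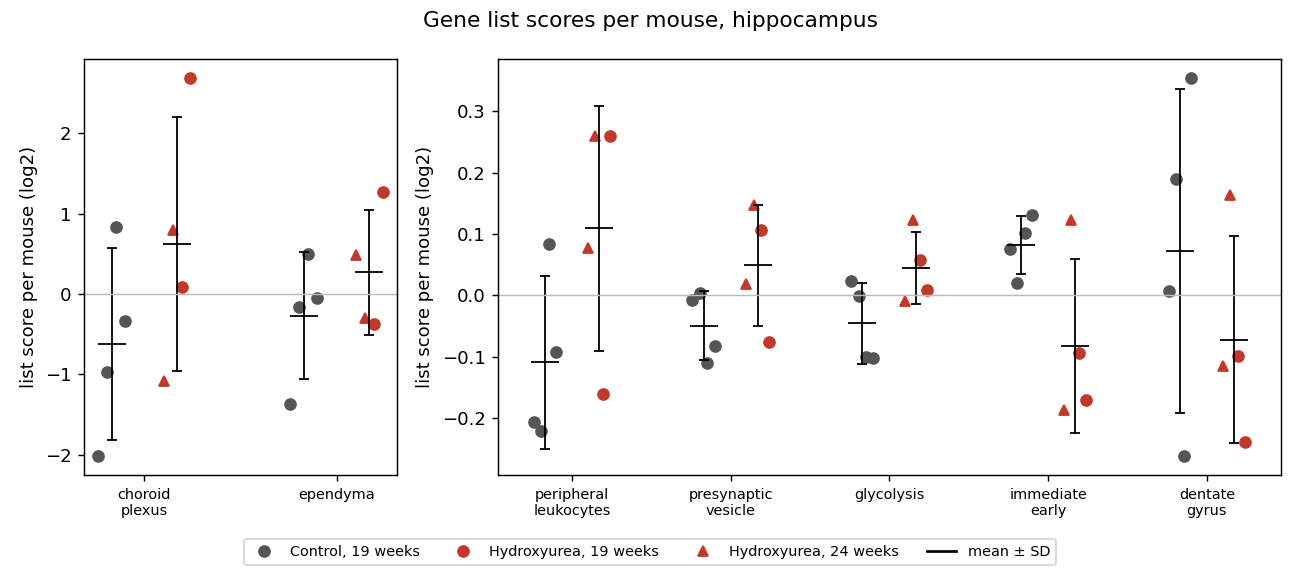
Score of 7 gene lists in each mouse, in log2 units around the mean of the 8 mice. Grey points are Control and red points Hydroxyurea mice, triangles mark the 24-week mice, and bars give mean ± SD over 4 mice. The choroid plexus score ran from -2.02 in Control 1 to 2.69 in Hydroxyurea 4.

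In all, 5 of 49 lists passed camera, 4 with higher and 1 with lower values, and 0 passed with an estimated correlation or with fry. The number was 10 without Control 3, 8 without Hydroxyurea 2 and 11 without Hydroxyurea 3. It was 6 without Control 1 and Hydroxyurea 2 together. Of the remaining 44 lists the adjusted p was 0.0579 to 0.962. Of growth factor genes, the values of Igf1r and of Vegfa, the endothelial growth factor (0.29 ± 0.07), passed limma when adjusted over the list alone (adjusted p = 0.0085 and 0.0237). Bdnf had -0.26 ± 0.15 and Tgfb1 0.24 ± 0.08. Vegfa also passed limma when adjusted over the hypoxia list alone (adjusted p = 0.045). Over all genes the limma adjusted p of both was 0.452. Of the 19 scores per mouse of cell types, regions, blood and leukocytes, 0 passed the exact permutation test. The lowest possible p of 0.0286, adjusted over 19 scores, does not let a single score pass, so this count says little. The smallest p found was 0.0571, for striatal genes, and its adjusted p was 0.875.

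Genes tied to the known actions of hydroxyurea on dividing cells did not pass as lists. Replication genes had 16 of 21 members lower (camera adjusted p = 0.357), DNA repair genes 18 of 26 (0.397) and p53 targets 17 of 23 (0.400). The replication score was 0.0030 to 0.067 in Control and -0.041 to -0.001 in Hydroxyurea mice (exact permutation p = 0.0286, the smallest possible). Its adjusted p was 0.764 over the 49 lists, an adjustment that does not let a single score pass. The replication list passed camera with the deposited value table. Cdkn1a, the cell cycle inhibitor downstream of p53, had -0.01 ± 0.17, with an exact permutation p of 1. Genes of mitosis had 11 of 17 members higher (camera adjusted p = 0.234), with Mki67 at 0.08 ± 0.12. Genes of neural progenitors and newborn neurons had 15 of 20 higher (0.357), with Neurod1 at -0.28 ± 0.08, Sox4 at 0.26 ± 0.10 and Dcx at -0.01 ± 0.13. The sign of Mki67 turned with median centring, and those of Dcx and Cdkn1a with normexp. A second probe of Neurod1 had the opposite sign, and the Sox4 value of Hydroxyurea 1 stood apart from its group.

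Stress and inflammation genes showed no list past the threshold in the main setting either. With the deposited value table the lists of NRF2 targets, antioxidant enzymes, ER stress and autophagy passed camera, the mitochondrial biogenesis list passed in 4 of 22 other settings, NRF2 targets also without Hydroxyurea 3, and cytokine genes with the choroid plexus score as a covariate. NRF2 targets had 18 of 23 members higher (camera adjusted p = 0.114), with Hmox1 at 0.08 ± 0.09 and Nqo1 at 0.19 ± 0.22. Hmox1 was -0.0058 with median centring. Sod2 had -0.02 ± 0.06. Genes of mitochondrial biogenesis had 17 of 21 lower (0.0845), with Gabpa at -0.23 ± 0.08 and Sirt1 at -0.29 ± 0.10. Cytokine genes had 11 of 16 lower (0.336), with Nfkb1 at -0.23 ± 0.06 and Nfkbia at -0.25 ± 0.13, and a second probe of Nfkb1 had the opposite sign. Alzheimer-linked genes had 13 of 26 higher (0.779), with App at -0.02 ± 0.07, Cdk5 at -0.25 ± 0.08 and Apoe at 0.23 ± 0.11. Control 1 stood apart for App and Hydroxyurea 2 for Apoe. Gfap of astrocytes had 0.24 ± 0.14 and Xist, expressed in females, -0.12 ± 0.11.

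The treated mice of 24 and of 19 weeks were set apart to ask whether expression differed between them. Per the labels, treatment began at 9 to 14 weeks of age and lasted 10 weeks. No untreated mouse was 24 weeks old, so age and start of treatment cannot be told apart. Hbb-b1 and Hba-a1, which encode haemoglobin chains of red cells, had log2 differences of 1.08 ± 0.19 and 0.83 ± 0.17 in the 24-week mice (SE, n = 2 per age; limma adjusted p = 0.840 and 1.0). Dsg2, a desmosomal cadherin, had 1.52 ± 0.18 and the nucleotidase gene Entpd4 0.87 ± 0.12. Bpifb6 had 1.06 ± 0.14 and Heatr9, well above background on 1 of 2 arrays at 19 weeks, 1.89 ± 0.26. Values below 0 were those of Slamf8, well above background on 1 of 2 arrays at 24 weeks (-3.44 ± 0.54), Hsbp1l1 (-1.02 ± 0.16) and the orphan receptor gene Esrrg (-0.58 ± 0.10). Gbx2 was not well above background at 24 weeks and was at least 1.5-fold higher at 19 weeks. It belongs to the thalamic list, whose score was 0.67 in the 19-week Hydroxyurea 3 and -0.27 to 0.10 in the other mice. Region content and age were not separated for it. Krt6b was not well above background on any of the 4 Hydroxyurea arrays. Cd46 was above it on 1 of them, and no fold is given for either.

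None of these age differences passed the threshold, and the smallest limma adjusted p was 0.480. At an unadjusted p under 0.05 there were 210 genes higher and 239 lower, against 830.9 in all by chance. Without Hydroxyurea 3, 1 gene passed, and without Hydroxyurea 4, 7 passed, with the lone 19-week mouse assumed to vary like the others. Slamf8 was among them, at -4.41 (adjusted p = 0.0062) and -2.46 (adjusted p = 0.0337). An exact test of 2 against 2 mice cannot go below p = 0.333. The Control mean of Hba-a1, 6.39, lay between the means at 24 weeks (6.87) and 19 weeks (6.04). The treatment value of Hba-a1 was 0.07 ± 0.23 over all mice and -0.35 among 19-week mice. Hbb-b1 had 0.17 ± 0.30 and -0.37.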

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

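The tests of dissection, of the noisy and the dim array, of the scaling's effect on direction and of treatment were chosen only after the results were seen.

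Choroid plexus genes had higher values in the treated group, with a difference of 1.25 in the list score that was 0.56 without Hydroxyurea 4 and 0.78 without Control 1. The score ranged over 2.85 among the 4 untreated mice alone, and the members moved together, at an estimated correlation of 0.935. Both are consistent with choroid plexus tissue carried over in dissection, although ependymal genes were also high in Hydroxyurea 1 (0.48), where the choroid plexus score was -1.08. Treatment stays open, since the exact permutation p of the score was 0.286, and slide row and cage stay open as untested. Age stays open in part. The list also passed camera in 19-week mice only (adjusted p = 5.7e-08) and with age as a covariate (adjusted p = 6.0e-08). These fits give the same fold changes, so the second is not a separate check. Both used the preset correlation (over all mice adjusted p = 0.826 with an estimated correlation). Both set Control against 2 treated mice of that age, of which Hydroxyurea 3 (0.09) lay within the range of the Control scores.

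Immediate early genes had lower values in the treated group, and scaling between arrays is argued against as the cause, because the list passed camera under 4 of 4 other scalings, with a highest adjusted p of 0.0404 at the preset correlation (adjusted p = 0.826 with an estimated correlation). With the dentate gyrus score as a covariate the median log2 fold change moved from -0.22 to -0.14, the spread of the members from 0.175 to 0.186 (SD), and the camera adjusted p to 0.120. The unadjusted camera p was 0.0221. A bound against a smaller share of dentate tissue was set beforehand. It was a median that kept a size of at least that of -0.11, with the unadjusted camera p under 0.05. The bound was met by less than the standard error of the median, 0.0497, a requirement added after the value was seen. That error treats the 22 members as independent, though their estimated correlation was 0.174, and is not a spread over mice. A smaller share of dentate tissue therefore remains open. Treatment remains open too, with an exact permutation p of 0.114 for the score, and 7 of 35 splits of the mice gave a camera p as small.

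The number of genes at an unadjusted p under 0.05 was 1642, mostly lower. Leaving out the noisy array Control 1 and the dim array Hydroxyurea 2 left 2.80 times the number that chance gives on average. The excess therefore did not rest on these arrays alone. The splits were not run without them, so 2.80 was not set against other groupings of the mice. The percentage of lower genes moved by 34.3 points over 4 scalings, so the scaling may set the direction, and with no filter on dim probes most were higher (1508 against 975). Chance cannot be excluded: 4 of 35 splits gave as many genes, and the highest of the other splits gave 1844. Treatment was not separated here from slide row, and no split tests it.

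For genes past an adjusted p of 0.05 with limma, where the real split gave 0 higher and 0 lower (586 and 1056 at an unadjusted p under 0.05), 35 of 35 splits gave as many in each direction, which a count of 0 fixes beforehand and which says nothing about chance, and the highest other count was 0. For lists past camera, 29 of 35 splits gave at least the 5 of the real split, and the highest other gave 18, so chance cannot be excluded for that count. Such numbers may come from a structure of the samples or from members that correlate above the preset 0.01 (0 lists passed with an estimated correlation), and these were not told apart by a test.

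In 13 of 270 groups of 4 values, 1 mouse lay far from the other 3 of its group, where chance gives about 1 in 20. In list scores, Control 4 had 0.067 for replication genes (others 0.0030 to 0.013). Control 1 had -0.17 for NRF2 targets (others -0.02 to 0.0050), -0.10 for autophagy genes (others -0.0016 to 0.0071) and 0.24 for clock genes (others -0.14 to -0.08). Hydroxyurea 4 had 0.021 for mitosis genes (others 0.052 to 0.054), and Hydroxyurea 3 had -0.021 for haem synthesis genes (others 0.013 to 0.016). The median variation of replicate spots was 12.1% on Control 1 (others 3.15% to 3.45%). In log2 signal, Control 1 had -1.49 for Rrm2b (others -1.15 to -1.13) and 6.29 for App (others 6.48 to 6.52). Control 3 had -4.89 for Bpifb6 (others -5.26 to -5.21). Hydroxyurea 4 had 2.20 for Otx2 (others -0.48 to -0.04), Hydroxyurea 1 had -0.086 for Sox4 (others 0.0043 to 0.016), and Hydroxyurea 2 had 7.38 for Apoe (others 6.96 to 7.03).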

How the results depend on the processing

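The normexp correction on the median signal, the covariate fits with list scores and the fit without Control 1 and Hydroxyurea 2 were added after the data were seen, the dentate gyrus covariate before its own result. The planned normexp correction of the mean signal was not run, and z scores gave counts only. The cause of the changes below was not tested, except where fewer arrays were fitted, the threshold itself was changed or arrays were centred on their median. Median centring subtracts another single number from each array. It therefore moved the fold changes of all genes with a value on every array by the same amount. The median gene went from -0.0038 to -0.086. The limma counts of genes past the adjusted threshold were 0 higher and 0 lower in every setting that kept an adjusted p. At an unadjusted p under 0.05 they were 586 higher and 1056 lower, and 449 genes for age. Leaving out 1 mouse gave 0 to 7 genes for age. None of Rrm1, Rrm2 and Rrm2b passed in any setting run. No marker score passed either, but that test could not call a single score. Its exact p cannot go below 0.0286, or below a higher value with fewer mice, before adjustment over 19 scores.

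The 5 lists past camera became 0 with an estimated correlation, 0 with fry, 3 with quantile scaling, 8 with normexp and 13 with the deposited value table, and 4 to 11 with 1 mouse left out. All 5 kept their direction in 22 other settings, leaving aside the choroid plexus list with its own score as a covariate, which removes its shift by construction. Immediate early genes passed in 16, choroid plexus in 18, leukocytes in 16, presynaptic and glycolytic genes in 11 each. Of lists that did not pass, glucocorticoid-induced genes did so in 10 of 22, with an adjusted p of 0.633 without Control 3, dentate gyrus genes in 7, ependymal genes in 6 and thalamic genes in 6, where the score difference of 0.25 was 0.07 without Hydroxyurea 3.

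With the replicate number as a block, 0 genes were higher and 0 lower by limma (563 and 754 at an unadjusted p under 0.05), 7 lists passed, and none of the 3 Rrm genes did. The numbers did not pair the mice: deviations of same-numbered mice correlated at 0.05, 0.20, -0.21 and -0.06, and only replicate 2 had each as the other's best partner.

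Of 1484 values of the 81 named genes, 1442 kept their direction and 42, in 12 genes, did not. No named gene passed the threshold in the main fits, so no call could turn. Many of these genes were named for a small p in these same arrays, so a kept sign is not independent support. With normexp, the sign of Cd46, too dim for a fold, turned (0.21, 24 minus 19 weeks), and Cdkn1a had 0.0035, Dcx 0.10 and Pot1b 0.0026. With median centring, Hba-a1 had -0.017, Hmox1 -0.0058, Mki67 -0.0017 and Rrm1 -0.070, and with quantile scaling Hba-a1 had -0.022. With 19-week mice only, and equally with age as a covariate, Cdkn1a had 0.16, Dcx 0.012, Sod2 0.011, Hba-a1 -0.35, Hbb-b1 -0.37 and Hmox1 -0.029. With array weights Cdkn1a had 0.12, Dcx 0.18 and Hmox1 -0.00067. With 1 mouse left out, ranges were -0.070 to 0.0075 for App, -0.082 to 0.14 for Cdkn1a, -0.093 to 0.085 for Dcx, -0.097 to 0.25 for Hba-a1, -0.080 to 0.37 for Hbb-b1, -0.046 to 0.34 for Nqo1, -0.020 to 0.068 for Rrm1 and -0.043 to 0.0033 for Sod2. Signal over background limits the dim genes: the 95% interval excluded a 1.5-fold change for 17.3% of genes well above background on 4 to 7 arrays and for 83.5% of those above it on all 8.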

Other observations

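Markers of neighbouring regions and of other cells varied between single mice. Thalamic genes were high in Hydroxyurea 3, with a score of 0.67 against -0.27 to 0.10 in the other mice. In that mouse Tnnt1, a troponin gene, had a log2 signal of 3.19 against -0.76 to 0.33 in the others, and Prkcd, a kinase gene of thalamic neurons, had 2.27. Ramp3 had 2.72 and Slitrk6 -0.96 there. Tnnt1, Prkcd, Ramp3 and Slitrk6 were chosen after their values were seen. Oligodendrocyte genes had scores of -0.31 in Control 2 and -0.48 in Hydroxyurea 2, where the other mice had 0.01 to 0.24.

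Erythroid genes had scores of 0.32 and 0.18 in the 24-week mice, -0.30 and -0.05 in the 19-week Hydroxyurea mice, and -0.20 to 0.14 in the Control mice.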
